A study of Mus musculus with 11 samples.

How the data were processed

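Ribosome profiling counts the mRNA fragments that translating ribosomes shield from nuclease, so a gene's footprint count rises with both its mRNA level and the number of ribosomes on each mRNA. The 11 libraries came from livers of C57BL/6 mice, 5 from mice fed ad libitum and 6 from fasted mice, taken at ZT4, ZT12 or ZT18 (zeitgeber time, hours after lights on). Per the labels' protocols, livers were homogenised in a buffer that held either 20 µg/ml cycloheximide, which stalls elongating ribosomes, or none (5 libraries with, 6 without). RNA outside ribosomes was digested with RNase I, the monosome fraction was taken from a sucrose gradient, and small RNA libraries were made. Reads were processed with STAR and SAMtools on the mm10 build, per the submitters' processing notes. Versions, the counting tool, the gene annotation, the treatment of reads that match several genes and the use of strand are not given in the sources used here. Footprints are short, so near-identical gene copies may share or lose reads in such counting. The length of the fast and the animal behind each sample are not given in those sources either, so p-values measure the spread between these samples.

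The deposited values are whole counts of footprints per gene, not normalised, for 9128 Ensembl gene identifiers. Per-library totals lay between 2271924 and 9099311 counts. No library held a value from 1 to 10, and the smallest value above 0 was 11 in each. A 0 may therefore mark a gene left out of that library's list, and is not read here as a measured absence. In all, 6157 genes had a count in every library and 2971 had at least 1 value of 0. The genes counted in every library held 97.5 to 98.7% of each library's counts. The reference table of GRCm38.p6 genes used here pairs no Ensembl identifiers with symbols, and 0 of the 9128 identifiers matched, so the files do not pair identifiers with names. For that reason the 26 pathway lists and 10 lists of other cell types fixed before the data were examined were not tested, no gene is named by symbol, and no check of gene length or GC content was made. Counts per gene hold no codon positions, so the planned tests of codon values were not run. No matched RNA-seq was used here, so translation and mRNA level were not separated.

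Samples were grouped by the feeding, time and lysis buffer labels. Each combination of the 3 factors held 1 library, and ad libitum at ZT4 with cycloheximide held none. The fit planned before the data were examined was edgeR's quasi-likelihood test on the counts (edgeR 4.0.16 with its default settings, R 4.3.3), with TMM factors, filterByExpr, and feeding, time and lysis buffer as additive terms over all 11 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Time was tested with an F test of both time coefficients and with 3 pairwise contrasts. A feeding effect that differs between times or between lysis buffers was tested by adding the interaction term. In this fit a 0 enters as a count of 0. After the zeros were seen, every comparison was also fitted to the 6157 genes counted in every library, and both counts are given side by side. This second set leaves out every gene listed at 0 in any library, genes that fell in 1 group included. Standard errors of log2 fold changes were taken as the size of the fold change over the square root of its F statistic. Levels are counts scaled to a common library total with TMM factors (CPM), and distances, correlations and principal components used log2 CPM with a prior count of 2 over the genes counted in every library. Library measures were compared by exact two-sided permutation tests, 10 in all, with Benjamini-Hochberg adjustment.

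The genes to name were fixed by a rule before the data were examined. For feeding it took those with the largest fold changes among called genes with a mean of at least 50 counts and the same direction in all 5 matched pairs of libraries of the same time and lysis buffer. For time it took the called genes with the largest fitted range and a mean of at least 50 counts. The rule was met by 7 genes higher and 16 lower in fasted liver and by 47 genes for time. Because the identifiers have no names here, only the first 2 in each direction are printed for feeding and the first 2 for time. A further 2 time genes were chosen from the genes counted in every library, after the data were seen. The rule's most abundant genes and list members are not printed for the same reason.

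The test was tried on simulated counts with each gene's mean over the libraries, the fitted spread at its level, the real totals and a seeded set of changed genes. No effect of time or lysis buffer and no library that stands apart was simulated. Recovery and false calls in the real data may therefore differ from those given here. For fasted against ad libitum over 6157 genes without zeros it recovered 20.9% of the 67 genes changed 1.5-fold, 80.6% of the 67 changed 2-fold and 100% of the 66 changed 4-fold, with 4 false calls. With the deposited zeros put back and 8650 genes tested, it recovered 5.97%, 25.4% and 86.4%, also with 4 false calls. The changed genes held no deposited 0 in either case, so recovery of genes with a 0 was not tried. Alternatives covered the scaling (DESeq2 size factors, library totals alone), the filter on low counts, limma-voom (limma 3.58.1), DESeq2 1.42.0, each library left out in turn, thinning to the smallest total, other covariates and subsets of libraries, and a minimum fold change of 1.5. Those added after the data were seen were the genes counted in every library, 0 as a missing value in limma, edgeR's newer quasi-likelihood method, a fit without the 2 libraries farthest from the rest, and a fit with libraries of the same feeding state and time summed into 1 sample. Figures were drawn with matplotlib 3.10.9.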

Results

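Liver ribosome footprints were compared between mice fed ad libitum (5 libraries) and fasted mice (6 libraries) at ZT4, ZT12 and ZT18, with cycloheximide in the lysis buffer for 5 libraries and without it for 6. Total counts per library ranged from 2271924 (fasted replicate 3, ZT12, with cycloheximide) to 9099311 (ad libitum replicate 4, ZT18, with cycloheximide). Fasted libraries held 5043659 ± 1866925 counts (SD, n = 6) and ad libitum libraries 7087266 ± 1208762 (SD, n = 5), exact permutation p = 0.0671 (two-sided, adjusted p = 0.336 over 10 tests). Fasted libraries listed 7536 ± 379 genes and ad libitum libraries 8114 ± 259 (SD, n = 6 and n = 5), exact permutation p = 0.013 and adjusted p = 0.13. Of 55 pairs of libraries, the most alike differed by a chi-square of 16.9 per degree of freedom, so no library was found deposited more than once. Whether libraries of the same feeding state and time came from 1 liver in different buffers is not given in the sources used here, so n counts libraries and may count an animal more than once. Across the genes counted in every library, 2 fasted libraries stood apart. The log2 level of fasted replicate 3 differed from the mean of the other libraries with an SD of 0.798 across genes, and that of fasted replicate 2 (ZT4, without cycloheximide, 3706568 counts) with an SD of 0.672. For the other 9 libraries this SD lay between 0.344 and 0.504. The first 3 principal components held 32.2%, 23.4% and 17.0% of the variance. The median share of a gene's variance was 9.95% for feeding (1 degree of freedom), 23.1% for time (2), 5.60% for lysis buffer (1) and 44.1% for the residual (6). Each median was taken over genes separately, so these shares do not describe a single gene. A term takes up some variance by chance, more with more degrees of freedom. No chance share was computed, so these shares do not rank the factors.

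**Figure D1:**
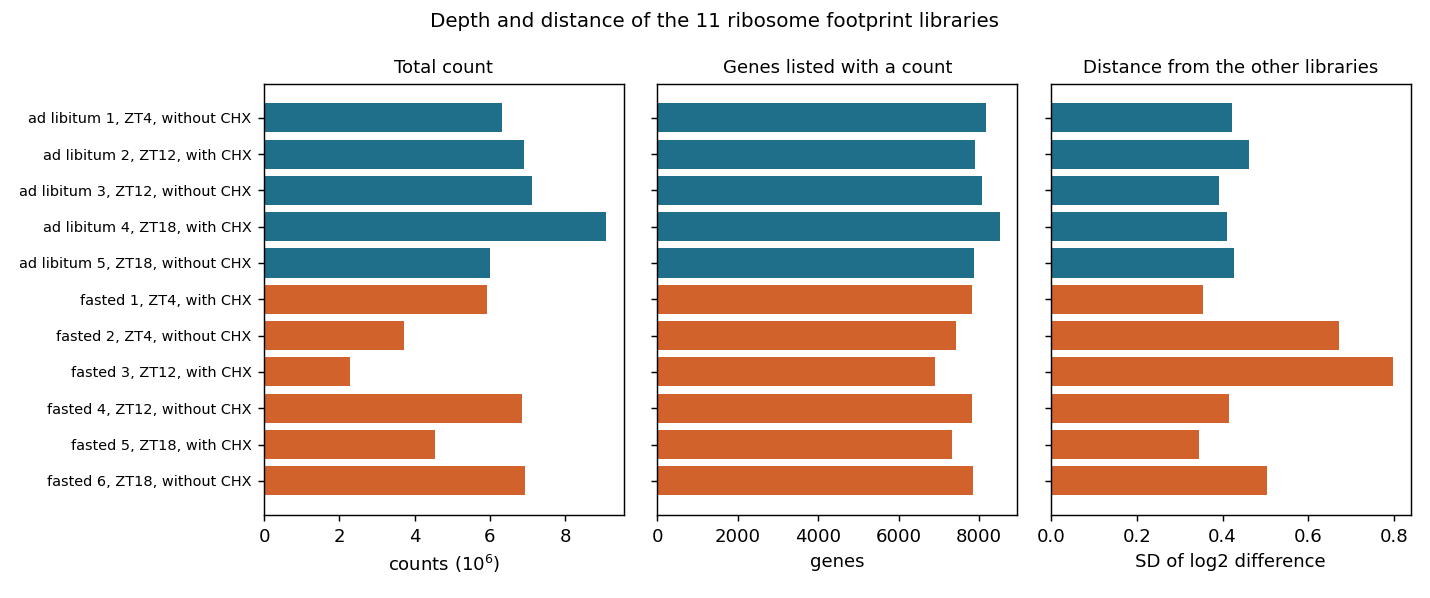
Total count, number of genes listed with a count, and SD across genes of the log2 difference from the mean of the other libraries, with 1 bar per library, ad libitum in blue and fasted in orange (CHX, cycloheximide in the lysis buffer). Fasted replicates 2 and 3 have the smallest totals, 3706568 and 2271924 counts, and the largest SDs, 0.672 and 0.798.

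The series compared liver translation between ad libitum feeding and fasting. The gene ENSMUSG00000072949 was higher in fasted liver, with 86.1 ± 51.3 CPM against 11.3 ± 3.38 in ad libitum liver (SD, n = 6 and n = 5), and every fasted library lay above every ad libitum library. Its fitted log2 fold change was 2.94 (SE 0.389, adjusted p = 0.0429, edgeR). ENSMUSG00000026853 was also higher, at 102 ± 39.0 against 26.1 ± 3.80 CPM (SD, n = 6 and n = 5), a log2 fold change of 2.00 (SE 0.304, adjusted p = 0.0499, edgeR). ENSMUSG00000060613 was lower, at 151 ± 117 CPM in fasted and 1140 ± 294 in ad libitum liver (SD, n = 6 and n = 5), a log2 fold change of -3.44 (SE 0.362, adjusted p = 0.0429, edgeR). ENSMUSG00000070047 had 276 to 577 counts in the 5 ad libitum libraries and was listed at 0 in all 6 fasted libraries. The planned fit called it by entering those unlisted values as counts of 0, so no fold or p is given. It belonged to 8 genes that were listed in all ad libitum libraries and in no fasted library, with mean ad libitum counts of 30.4 to 377. The reverse held for 0 genes, while fasted libraries listed fewer genes in all (7536 against 8114 on average) and had smaller totals. Of the 462 ways to choose 5 of the 11 libraries, 1, the ad libitum libraries, gave as many as 8 genes listed in all of them and in no other, and the next gave 7.

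**Figure D2:**
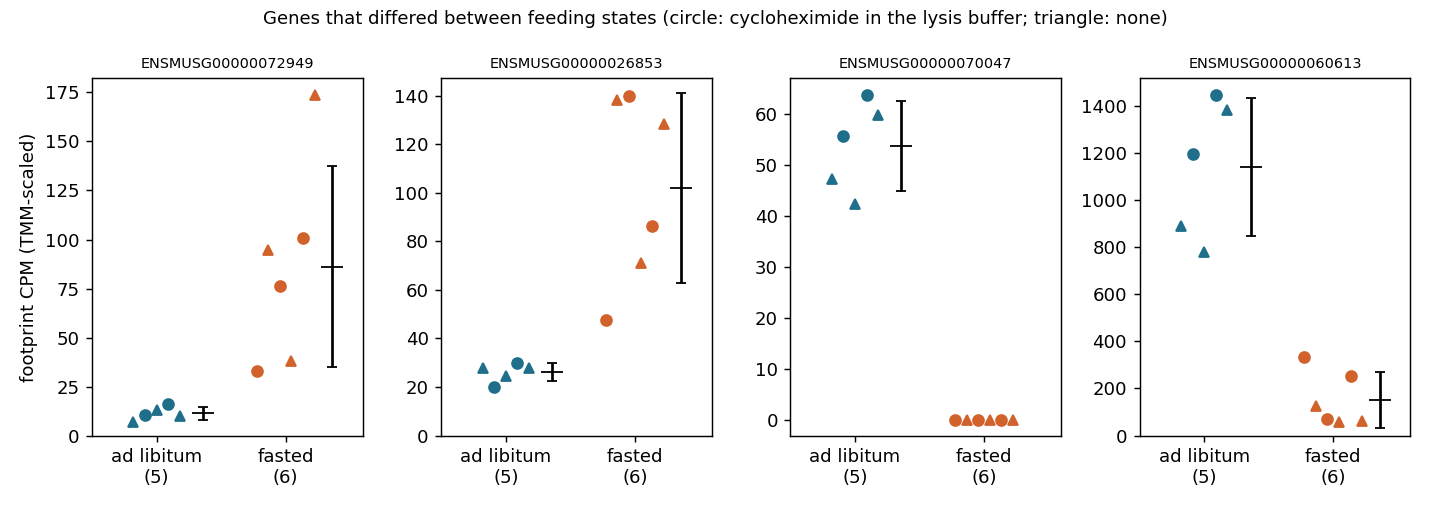
Footprint CPM after TMM scaling for 4 genes in the 5 ad libitum and 6 fasted libraries, with 1 point per library and the mean and SD beside them (linear axes, circles with and triangles without cycloheximide in the lysis buffer). For ENSMUSG00000060613 the ad libitum libraries lie between 781 and 1450 and the fasted between 57.6 and 335, and ENSMUSG00000070047 is listed at 0 in all 6 fasted libraries, without a mean.

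Over all genes, 23 of 8672 tested differed between fasted and ad libitum liver, 7 higher and 16 lower in fasted, at an adjusted p under 0.05 in edgeR. At an unadjusted p under 0.05 there were 1151 genes, against 434 that chance alone would give. Among the 6157 genes counted in every library, a set chosen after the zeros were seen, 200 differed, 81 higher and 119 lower in fasted liver. These included 22 of the 23, and the other gene had values of 0. Their median absolute log2 fold change was 1.06, with a range from -3.42 to 5.55, and 46 of the higher and 65 of the lower genes changed more than 2-fold. In this set ENSMUSG00000072949 had a log2 fold change of 2.96 (SE 0.358, adjusted p = 0.00444), ENSMUSG00000026853 of 2.02 (SE 0.291, adjusted p = 0.00693) and ENSMUSG00000060613 of -3.42 (SE 0.330, adjusted p = 0.00179), all in edgeR. The 81 higher genes held 1.75 ± 0.255% of counts in ad libitum and 4.73 ± 1.62% in fasted libraries, and the 119 lower genes 4.08 ± 0.456% and 1.89 ± 0.558% (SD, n = 5 and n = 6). The genes were called in these same libraries, so the direction of both differences follows from that choice. Of 4 classes of equal size by mean level, the most abundant held 31 of the higher and 51 of the lower genes, and the least abundant 14 and 20. Changes are easier to call at higher counts, so these numbers do not show that abundant genes changed more.

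Both feeding states were sampled in 5 matched pairs of libraries of the same time and lysis buffer. The log2 differences of pairs of different times correlated across the 6157 genes with r between 0.227 and 0.521, and those of the 2 pairs of the same time with r = 0.270 at ZT12 and 0.649 at ZT18. The value of 0.521 joined the ZT12 pair with cycloheximide and the ZT4 pair, which hold fasted replicates 3 and 2, the libraries that stood apart. The ZT4 pair had r = 0.231 with the ZT12 pair without cycloheximide. With the ZT18 pairs it had r = 0.498 (with cycloheximide) and 0.438 (without). Genes are not independent replicates, and pairs of the same time may share livers. Calls made from ZT12 and ZT18 alone could be read in the ZT4 libraries, whose counts did not enter the fit. Over all genes that fit called 0 of 8544 (1133 at an unadjusted p under 0.05), and among the genes counted in every library, which by that choice also had a count at ZT4, it called 165. Of those 165 genes (53 higher, 112 lower in fasted), 156 (94.5%) differed in the same direction in the ZT4 pair, compared with 68.0% of all genes. That pair holds fasted replicate 2 and the fit held fasted replicate 3, the libraries that stood apart. A deviation shared by these 2 could add to the agreement. Fasted replicate 1 (ZT4, with cycloheximide) has no matched ad libitum library and was not read. The median size was 1.21 on the log2 scale at ZT12 and ZT18 and 1.01 in the called direction at ZT4.

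The number of genes called for feeding depended on the fit and on single libraries. With libraries of the same feeding state and time summed into 1 sample, 3 against 3, 0 of all genes were called (1110 at an unadjusted p under 0.05) and 193 of those counted in every library, 130 of them among the 200. In the fit to all genes, the matched pair as a block gave 0 genes, library totals alone gave 50 (21 higher, 29 lower) and DESeq2 gave 759. Without the 2 libraries that stood apart there were 45, 13 of them among the 23. Leaving out ad libitum replicates 1 to 5 in turn gave 9, 0, 0, 0 and 0 genes, and leaving out fasted replicates 1 to 6 gave 84, 0, 6, 4, 0 and 0. Among the genes counted in every library, the matched pair as a block gave 406, DESeq2 gave 526, and without the 2 libraries that stood apart there were 679 (327 higher, 352 lower), the 200 among them. Leaving out ad libitum replicates 1 to 5 in turn left 54, 55, 60, 51 and 55 genes, and leaving out fasted replicates 1 to 6 left 486, 107, 301, 315, 49 and 33. In both sets the block fit also left out fasted replicate 1, which has no matched ad libitum library. Without that library and without the block there were 84 and 486 genes, so the rise from 200 to 406 cannot be credited to the block. The genes ENSMUSG00000072949, ENSMUSG00000026853 and ENSMUSG00000060613 kept their direction in every alternative run. Over all genes they lost the call in 15, 18 and 14 of 28 alternatives, with adjusted p up to 0.464, and in the set counted in every library they kept it in all 25.

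Livers were taken at 3 times of day. Among genes counted in every library, ENSMUSG00000059824 had 163 ± 31.9 CPM at ZT12 (SD, n = 4), 8.11 ± 4.12 at ZT4 (n = 3) and 10.4 ± 1.93 at ZT18 (n = 4). Its log2 difference between ZT12 and ZT4 was 4.38, and its adjusted p over the 3 times was 3.42e-06 (edgeR F test). ENSMUSG00000058672 had 12.5 ± 5.71 CPM at ZT12 (SD, n = 4), 149 ± 65.0 at ZT4 (n = 3) and 104 ± 28.2 at ZT18 (n = 4). Its log2 difference between ZT12 and ZT4 was -3.46, and its adjusted p over the 3 times was 0.000342 (edgeR F test). ENSMUSG00000032010 was listed at 0 in all 3 libraries of ZT4 and had 169 to 618 counts in the 4 of ZT12 and 160 to 335 in the 4 of ZT18. ENSMUSG00000055116 was listed at 0 in all 4 libraries of ZT12 and had 199 to 477 counts at ZT4 and 143 to 288 at ZT18. The planned fit called both, but it entered the unlisted values as counts of 0, so no p is given for them. All 4 patterns were present in libraries of both feeding states.

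**Figure D3:**
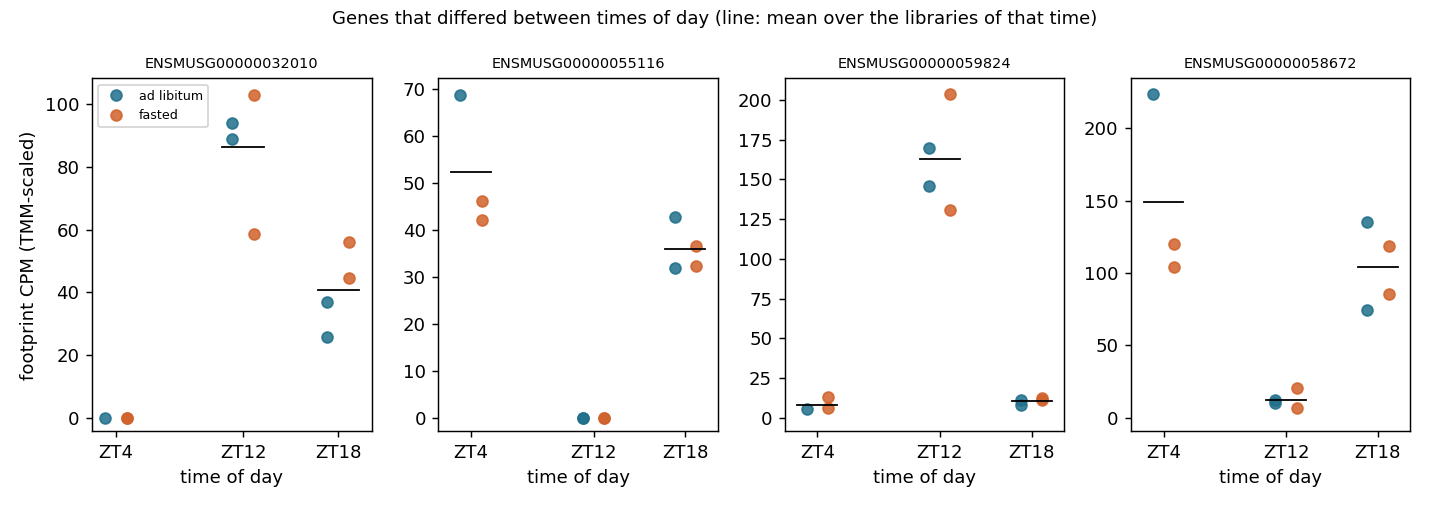
Footprint CPM after TMM scaling by time of day for 4 genes, with 1 point per library, ad libitum in blue and fasted in orange, and a line at the mean of each time where the gene was listed (linear axes). ENSMUSG00000059824 lies between 131 and 204 at ZT12 and at 12.8 or below in every library of the other times, and ENSMUSG00000055116 is listed at 0 in all 4 libraries of ZT12.

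Over all genes, 48 differed between times in edgeR's F test, 10 of them with values of 0, and 1098 had an unadjusted p under 0.05, against 434 by chance. Among the genes counted in every library there were 77, of which 37 were among the 48. Of the 77, 24 had their highest fitted level at ZT4, 22 at ZT12 and 31 at ZT18, while 30 had their lowest at ZT4, 40 at ZT12 and 7 at ZT18. The median fitted range over the 3 times was 1.36 on the log2 scale, and 73 of the 77 ranged more than 2-fold. Between ZT4 and ZT12, 53 genes rose and 41 fell. Between ZT12 and ZT18, 48 rose and 15 fell, and ZT18 differed from ZT4 in 9 genes, 8 of them higher. The corresponding numbers over all genes were 14 and 20, 30 and 4, and 11 with 10 higher. Over all genes, DESeq2 called 752. Without the 2 libraries that stood apart edgeR called 65 of all genes, 36 of them among the 48. With libraries of the same state and time summed edgeR called 0 (1207 at an unadjusted p under 0.05). Without ad libitum replicates 1 to 5 in turn, 31, 25, 21, 24 and 27 of all genes were called, and 24 and 27 without fasted replicates 5 and 6. In the set counted in every library, DESeq2 called 488 and 618 were called without the 2 libraries that stood apart, the 77 among them in both, and the summed libraries gave 123, 54 of them among the 77. Leaving out ad libitum replicates 1 to 5 in turn gave 28, 32, 23, 25 and 39 genes there, and 231, 279 and 25 were called without fasted replicates 1, 3 and 5.

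The lysis buffer comparison asked whether the drug in the buffer changed footprint counts per gene. The sample titles carry the number 1 in every library with the drug and 2 in every library without it, so the buffer and whatever that number marks cannot be told apart. In edgeR 0 of 8672 genes differed between libraries made with and without cycloheximide (543 at an unadjusted p under 0.05, 434 by chance, smallest adjusted p = 0.773), and 0 of the 6157 genes counted in every library did (597 against 308 by chance, smallest adjusted p = 0.385). For both sets limma-voom also called 0, while DESeq2 called 101 (71 higher, 30 lower with the drug) and 19 (14 higher, 5 lower). Without the 2 libraries that stood apart, edgeR called 3 genes, all higher with the drug, in the set counted in every library. Libraries of the same feeding state and time made in different buffers correlated across genes with r = 0.987 and 0.988 for ad libitum at ZT12 and ZT18, and with r = 0.916, 0.892 and 0.973 for fasted at ZT4, ZT12 and ZT18. The SDs of their log2 differences were 0.303 and 0.290 in ad libitum, and 0.758, 0.860 and 0.444 in fasted liver. The fasted pairs at ZT4 and ZT12 hold the libraries that stood apart, fasted replicate 2, made without the drug, and fasted replicate 3, made with it. The differences of separate pairs correlated with each other at r between -0.32, for those 2 pairs, and 0.34.

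Feeding, time and lysis buffer were crossed, so the difference between feeding effects could be tested itself. A feeding effect that differed between times was called by edgeR for 0 of 9032 genes (202 at an unadjusted p under 0.05, 452 by chance), and for 0 of the 6157 genes counted in every library (161, 308 by chance). DESeq2 called 61 and 5 and limma-voom 0 and 0, and without fasted replicate 4 edgeR called 127 over all genes. A feeding effect that differed between lysis buffers was called by edgeR for 0 of 8672 and 0 of 6157 genes (193 and 170 at an unadjusted p under 0.05). DESeq2 called 141 and 2 and limma-voom 0 and 0, and without fasted replicate 1 edgeR called 8 over all genes.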

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

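In each feeding state, 6 library measures (total count, genes listed, share of the 10 largest genes, TMM factor, distance from the other libraries and share of counts in the genes counted in every library) and the levels of the 3 named feeding genes that had a count in every library were searched for a library far from the rest of its group by Dixon's test. Of 18 groups of values tested, 0 passed the critical value, where chance gives about 1 in 20. Fasted replicate 3 came closest among library measures of fasted liver, with a gap over range of 0.500 for the share of counts in the genes counted in every library, below the critical value for 6 libraries. In ad libitum liver the total of replicate 4, 9099311 counts, had a gap over range of 0.644, below the critical value for 5. Each group mixes times of day, and the 2 fasted libraries that stood apart can mask each other in a test of single libraries, so 0 passes do not show that no library differs. With 0 genes called for a feeding effect that differs between times or lysis buffers in edgeR (202 and 193 at an unadjusted p under 0.05, 61 and 141 in DESeq2, 0 in limma-voom), no gene's feeding effect was singled out either.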

How the results depend on the processing

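Fits to the genes counted in every library, with 0 as missing, with edgeR's newer method, without the 2 libraries that stood apart, and with libraries of the same state and time summed were chosen after seeing the data. The cause of each change was not tested, and some of these fits held fewer libraries or genes. Feeding over all genes called 23; it moved to 50 with library totals alone, 49 with a mean of at least 50 counts (6430 genes tested), 90 with limma-voom, 90 with the newer method, 759 with DESeq2, 220 with 0 as missing, 200 in the genes counted in every library, 45 without the 2 libraries, 11 with feeding alone, and 0 with the matched pair as a replicate block, in the libraries without cycloheximide, at ZT12 and ZT18 only, with summed libraries, or with a fold above 1.5. Leaving out 1 library gave 0 to 84. Its 200 in the genes counted in every library moved to 526 with DESeq2, 679 without the 2 libraries, 44 with feeding alone, 406 with the block, 114 in the libraries without cycloheximide, 23 with a fold above 1.5, and 33 to 486 with 1 library left out. In both sets the block fit also left out fasted replicate 1. Leaving out that library without the block gave 84 and 486. Time called 48 over all genes and moved to 77 with limma-voom, 752 with DESeq2, 114 with 0 as missing, 77 in the genes counted in every library, and 0 in ad libitum only, fasted only or summed libraries (21 to 68 with 1 library left out). The latter 77 moved to 51 with library totals alone, 488 with DESeq2, 618 without the 2 libraries, 2186 in ad libitum only, 0 in fasted only, 123 in summed libraries, and 23 to 279 with 1 left out. The 0 calls for the lysis buffer became 101 with DESeq2 over all genes, and 19 with DESeq2 and 3 without the 2 libraries in the genes counted in every library (0 to 0 with 1 left out in both sets). The feeding by time interaction became 61 and 5 with DESeq2, and 0 to 127 and 0 to 0 with 1 left out. It could not be fitted without ad libitum replicate 1. The feeding by lysis buffer interaction became 141 and 2 with DESeq2, and 0 to 8 and 0 to 0 with 1 left out. Size factors of DESeq2 and thinning to the smallest total kept each count within 1.5 times, and none of the 5 named genes counted in every library reversed; the 3 with values of 0 were not followed. The time genes ENSMUSG00000059824 and ENSMUSG00000058672 lost their call in 1 of 22 alternatives, fasted only (adjusted p = 0.0809 and 0.731, edgeR F test over the 3 times). There their log2 differences between ZT12 and ZT4 were 4.195 and -3.123, against 4.378 and -3.457 with all libraries. Each matched pair shares a time, a buffer and the number in its titles, which follows the buffer. With the mean of each state and time removed, same-numbered libraries of both states deviated with r = 0.074 at ZT12 and 0.0077 at ZT18 across genes, and ZT4, with 1 ad libitum library, allows no such test. Over all pairs of states and times these r ran from -0.32 to 0.34, so whether the matched libraries share more than their time, buffer and number stays open. List and codon tests were not run. No value under 11 was listed. In simulated counts, 2-fold changes in genes without a 0 were recovered in 80.6% when only such genes were tested. The share was 25.4% when genes with zeros were tested beside them. Recovery of genes that hold a 0 was not simulated, nor were effects of time or buffer or libraries that stand apart.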

Other observations

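The tests of whether a 0 means no footprints, of a shared response and of a wrong label, and the splits of summed libraries, were chosen only after the results they concern were seen.

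The feeding count over all genes was 23 with the deposited zeros as counts and 220 with them as missing in limma, and with them as counts limma-voom, the newer method of edgeR and DESeq2 called 90, 90 and 759. In the genes counted in every library edgeR, limma-voom and the newer method called 200, 213 and 206, so these 3 differed less there, while DESeq2 called 526. Over 9128 genes and 11 libraries there were 14621 values of 0, 3538 values from 11 to 20 and 0 values from 1 to 10. This gap argues against reading every 0 as a library without footprints of the gene. It restates the smallest listed value and cannot tell which single 0s stand for no footprints. A candidate explanation is a minimum that was applied to each library's list. In the 710 genes with a single 0, the count expected there from the other libraries lay below the smallest listed count in 55.8%, where 9.09% would be chance, yet short of the 75% set beforehand for a minimum alone. The median expected count there was 30.9, above the smallest listed value of 11, so what rule wrote the zeros stays open. The number of zeros ran from 604 in the library of 9099311 counts to 2210 in that of 2271924, and the fitted biological coefficient of variation was 0.565 with all genes and 0.250 in the genes counted in every library.

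Fasted replicates 2 and 3 differed from the remaining libraries more than any other library did. Thinning every library to 2271924 counts left their SDs at 0.671 and 0.786, and the largest SD of the other 9 was 78.4% of the smaller of these (77.7 to 79.0% over 10 draws), below the 80% set beforehand, which argues against depth as the whole cause. Were a response shared by the libraries of the same state and time the whole cause, fasted replicates 1 and 4 would stand apart too. They are among the other 9, with SDs of 0.355 and 0.415, which goes against it. This is the first observation read again, not a separate test. The difference within these pairs, at least 1.71 times the largest of the other 3, follows largely from those distances and is not separate evidence. Of the genes called outside their matched pairs, 94.6% of 167 and 90.0% of 180 differed in the called direction within the pair. This goes against a wrong feeding label for each taken alone. Each stayed in the fit that judged the other, so a deviation shared by the 2 could raise these shares. No share over all genes was computed beside them. The state of single animals, handling and admixed cells may still account for the distance and stay untested, the last because marker genes could not be identified here.

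Among the ad libitum libraries alone, 2186 of the genes counted in every library differed with time in edgeR, and among the fasted alone 0 (238 at an unadjusted p under 0.05). The test of the difference itself, feeding by time, called 0 genes (161 at an unadjusted p under 0.05, 5 in DESeq2, 0 in limma-voom), so the feeding states are not shown to differ in their response to time. The ad libitum fit had 1 residual degree of freedom, its libraries of the same time may share a liver, and over all genes with zeros it called 0 (2614 at an unadjusted p under 0.05). A hypothesis is that time effects ran in the same direction in both states and were hidden by the spread between fasted libraries. Of the 2186 genes, 61.4% differed between ZT12 and ZT18 in the same direction in fasted liver, against 57.0% of the uncalled genes, which lies between the 60% and 75% set beforehand and leaves it open. In the same genes r across genes between the states was 0.409, against 0.299 over all genes, and without fasted replicate 3 the share was 68.5% and r 0.481, values that go with the hypothesis and were computed without a bound set for them. With time alone in the model the 15 splits of the 5 ad libitum libraries are too few to reach a share under 0.05 (1 as large, 1297 genes against at most 75 in the others).

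Other splits of the 11 libraries into groups of the same sizes gave a measure of how often chance yields as many genes. For feeding, 1 of 99 splits, the real one, reached the real counts, with 23 genes against at most 5 over all genes and 200 against at most 63 in the genes counted in every library, a share below 0.05. For time, 2 of 100 splits, the real one included, were as large in both sets, also below it. The splits were drawn without regard to the other terms kept, so they overlap with those terms to unlike degrees and are not fully comparable. Beyond that limit, these shares exclude chance only if the libraries are separate samples. If those of the same state and time came from 1 liver, summing them leaves 6 samples, over all genes the counts fall to 0 for feeding and 0 for time (1110 and 1207 at an unadjusted p under 0.05), and in the genes counted in every library 193 and 123 were called. The highest other splits of those 6 samples called 0 and 2 genes, but with 10 and 15 splits, of which 1 was as large in each case, no share under 0.05 can be reached. Over the 11 libraries the real time counts were 48 and 77, and the highest other split called 761 and 384, several times as many. The cause of this was not tested. That split lay along the lysis buffer, with 1 group all with the drug and the others all without it except fasted replicate 3, a library that stood apart and that alone then separated the buffer from the groups. For the lysis buffer the real count was 0 in both sets, which all 100 splits reach by construction, so the splits decide nothing there. The highest others called 100 and 700, and that split placed fasted replicates 2 and 3, the libraries that stood apart, in the same group.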
